A study of Rattus norvegicus with 18 samples.

How the data were processed

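Total RNA of rat kidney, extracted with Trizol from tissue kept in liquid nitrogen, was labelled with biotin and hybridized to Affymetrix rat arrays. The labels place 18 arrays in 6 groups of 3, normal saline and cadmium at 1 day, 6 weeks and 12 weeks. They give neither the dose nor the route nor the hour of harvest, and they do not say that replicate numbers pair animals. The data did not show such pairs either. Correlations of deviations from the group means lay between -0.469 and 0.433 for the same replicate number, with 2 of 9 over 0.1. For different numbers they lay between -0.528 and 0.515, with 6 of 18 over 0.1. With 3 arrays per group this cannot exclude pairing.

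The deposited values are log2 signals per probe set. The authors' summarization and normalization are not stated. From the data, values run from 1.78 to 19.93 and 9 columns share a ceiling of 19.9315. Since the scale may have been stretched, a difference of log2 values was not read as a calibrated fold. No detection calls were available, and arrays have no depth in reads: the number of arrays and the signal over background limit the precision. The background level, 4.22, was the 95th percentile of 1276 odorant and vomeronasal receptor genes (median 3.46), a choice made after the data were seen. A bound ("at least") is the brighter group's mean minus this level. Of the genes tested 13985 had a mean above it and 23 lay within 0.5 of the ceiling.

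The table held 70570 probe sets, of which 186 were controls, 23437 had 1 gene name, 505 several and 46442 none. A gene was a symbol held by a probe set that names 1 gene, and where several probe sets named it (1182 genes) the one with the highest mean over all arrays stood for it, which gave 22084 genes. Symbols came from the probe annotation of the series, and 22068 of 22696 Entrez identifiers were found in the RefSeq table of the rat. Positions are not given, since no genome came with the data. No filter on dim genes was applied. Probe sets with several names or none were left out except in 1 alternative.

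Group means of all 18 arrays were fitted per gene in limma 3.58.1 (R 4.3.3, with data.table version 1.17.8) with lmFit, contrasts.fit and eBayes, 12 residual and 2.45 prior degrees of freedom, two-sided, and a Benjamini-Hochberg adjusted p under 0.05 over the 22084 genes within each contrast. The contrasts were cadmium against saline at each time and averaged over times, the 3 differences of the cadmium change between times, and the 3 comparisons of saline between times. An adjusted p in the text is from limma unless another test is named. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

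In addition 31 gene lists were tested with camera in limma (preset correlation 0.01), again with an estimated correlation, and with fry. The p values were adjusted over 93 tests, 31 lists at 3 times, in each family of contrasts, and over 31 for the average. Camera compares a list with all other genes, and fry tests whether a list's genes move one way on balance. Over the 3 times camera called 35 lists, 9 at 1 day, 15 at 6 weeks and 11 at 12 weeks. With an estimated correlation only interferon response at 6 weeks held. The lists covered metal handling, antioxidant genes, heat shock proteins, endoplasmic reticulum stress, p53 targets, tubular injury, proximal tubule transport, fatty acid oxidation, the respiratory chain, inflammatory signalling, interferon response, extracellular matrix, cell cycle, cholesterol synthesis, calcium with phosphate and vitamin D, iron handling, autophagy with lysosome, circadian clock, glucocorticoid response, immediate early genes, distal nephron with collecting duct, podocytes, endothelium, macrophages, lymphocytes, neutrophils, red blood cells, adipose tissue, adrenal cortex, urothelium and sex-linked genes. Median, mean and test differed in sign for metal handling, p53 targets and iron handling at 1 day, heat shock proteins at 6 weeks, and metal handling, endoplasmic reticulum stress, autophagy, adipose tissue and sex-linked genes at 12 weeks. Of the lists' members Atf3, Btg2, Pck1 and Per1 stand in more than 1 list. The macrophage, lymphocyte, neutrophil, red blood cell, adipose, adrenal and urothelial lists serve as markers of other cell types in a whole kidney.

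Named genes followed a rule fixed before the data were examined: every measured metal handling gene; for each cadmium comparison the 8 largest rises and 8 largest falls among passing genes with separate groups and a proper symbol, or the 4 smallest p values in a direction without any; up to 4 members of each list described, with the smallest p; and 5 per direction, or 3 not passing, in the other contrasts. Oasl, LOC102549184, Slc5a2, Dbp and, at some times or contrasts, Abcc3, Hmox1 and Bmal1 were named outside it, after their values were seen, and the calls of Oasl and Abcc3 at 12 weeks and of LOC102549184 were not followed through the alternatives. The design, lists, alternatives and rule were fixed before the data were examined. The alternatives were quantile normalization, median centring, leaving out the dimmest 33% of genes (14722 left), the mean of a gene's probe sets, every probe set (70384), trend and robust fitting, array weights, the replicate number as a block, only the arrays compared, and leaving out each array. An offset of 16 for linear values did not apply to log2 values and was not run. Covariates for the clock (Bmal1 minus Dbp) and for proximal tubule transcripts were added after the data were seen.

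The procedure was tested on simulated data, normal noise with each gene's fitted spread and many genes moved at once. In it 28.4% to 34% of randomly drawn genes moved by 0.5 log2 units passed. Of those moved by 1, 78.8% to 82.4% passed, and of those moved by 2, 95.2% to 96.8%. Moving many genes at once eases the adjusted threshold, so fewer would pass where few genes change. False calls made up 4.48% to 5.50% of all calls there. The noise was drawn independently for each gene and array. Genes of real arrays can vary together, so this share need not hold for them.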

Results

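Kidney RNA of Sprague-Dawley rats given cadmium chloride or normal saline was measured on Affymetrix arrays after 1 day, 6 weeks and 12 weeks. Cadmium is a heavy metal that collects in the kidney, chiefly in the proximal tubule. Each of the 6 groups held 3 arrays, labelled as biological replicates, 18 arrays in all. The array medians lay between 4.03 and 4.26 on the deposited log2 scale, and 2 arrays of a group correlated at 0.982 to 0.995 across genes, against 0.979 to 0.995 for 2 arrays of different groups. The number of arrays limits the precision of every value below. Changes are differences of mean log2 signal, cadmium minus saline, and are not calibrated folds, since how the arrays were summarized is not stated and the scale ends at 19.93. Odorant and vomeronasal receptor genes, taken as mostly silent in kidney, set a background level of 4.22.

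The comparison at 1 day asks what the kidney shows soon after the first exposure. No gene passed. The 4 genes with the smallest p among the higher ones were Pbk-ps1 (0.57, adjusted p = 0.538), Olr1242 (0.63), Tesl (0.64) and Vom1r62 (0.43), all with means at the background level in both groups. Among the lower ones they were Or9g3 (-0.75, adjusted p = 0.538) and Prl8a2 (-0.38), both at background, Or1f19 (-0.54) and Mest (-0.81). Hmox1, which breaks down heme and is induced by many metals, was -0.04 apart (SE 0.55). In limma 0 of 22084 genes passed in either direction, and 433 had an unadjusted p under 0.05, where chance alone gives about 1104.2. In simulated data of this size 78.8% of randomly drawn genes moved by 1 log2 unit passed at 1 day, and 34% of those moved by 0.5. Many genes were moved at once there, which eases the adjusted threshold. Where few genes change, a smaller share would pass. The simulated noise of a gene also had the same spread in every array and was independent between genes, which need not hold for real arrays.

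Gene lists fixed before the data were examined moved little at 1 day. Heat shock proteins, chaperones that refold damaged proteins, had 14 of 16 members on the higher side with a mean change of 0.21 (camera adjusted p = 7.22e-06, adjusted p = 0.197 with an estimated correlation). Their smallest p values belonged to Chordc1 (0.44) and Hspb1 (0.32), and Hsph1 was 0.72 apart, none of which passed. The endoplasmic reticulum stress and amino acid response list had 13 of 18 on the higher side with a mean of 0.13 (adjusted p = 4.99e-04, adjusted p = 0.467 with an estimated correlation), led by the chaperone Hsp90b1 (0.55). Inflammatory signalling had a mean of 0.08 (adjusted p = 0.0483, and 0.573 as adjusted p with an estimated correlation). Red blood cell genes had a mean of -0.42 with 0 of 9 above 0 (adjusted p = 2.91e-04, adjusted p = 0.467 with an estimated correlation). Interferon response had a mean of -0.20, cell cycle -0.16, cholesterol synthesis -0.18, extracellular matrix -0.24 and sex-linked genes -0.34. Their camera adjusted p values were 9.26e-04, 0.00153, 0.00501, 0.0405 and 0.0376, and with an estimated correlation the adjusted p values were 0.544, 0.705, 0.544, 0.874 and 0.544. No member of any list passed at 1 day, over all genes or adjusted over the list alone. Leaving out 1 of the 6 arrays moved the mean of each of these 9 lists by over 1.5 times. Heat shock proteins ran from 0.09 without cadmium replicate 3 to 0.32, and endoplasmic reticulum stress from 0.06 to 0.18, both with their calls kept.

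The other 7 lists called at 1 day lost their call without at least 1 array. Red blood cells stood at -0.22 without cadmium replicate 3, where their call ended. Inflammatory signalling ran from -0.02 to 0.16 (call ended in 3 of 6), interferon response from -0.41 to -0.07 (2), cell cycle from -0.22 to -0.08 (2) and cholesterol synthesis from -0.24 to -0.10 (2). Extracellular matrix ran from -0.53 to 0.22 and was called in the other direction without saline replicate 3. Sex-linked genes ran from -0.55 to 0.03 and turned without saline replicate 1 (adjusted p = 0.559). Cadmium replicate 3 of 1 day stood apart from the other 2 in Bmal1 minus Dbp (-1.81 against -6.85 and -5.62) and in the mean of proximal tubule transport (12.54 against 14.10 and 14.54).

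At 6 weeks interferon-induced genes rose with cadmium. Irf7, the transcription factor that drives interferon production, stood at 10.13 ± 0.44 (SD, n = 3) with cadmium and 7.12 ± 0.50 with saline, a log2 change of 3.01 (SE 0.41, limma adjusted p = 0.0201). Mx1, an antiviral GTPase, rose by 2.17 (SE 0.22, adjusted p = 0.00104), and Usp18, which removes the ubiquitin-like protein ISG15 from its targets and restrains interferon signalling, rose by 1.58 (SE 0.16, adjusted p = 0.00104). Isg15 itself rose by 0.77 (SE 0.12, adjusted p = 0.0485). All 19 of 19 measured members of the interferon list were higher, with a mean of 1.35. Of these, 4 passed over all genes and 17 adjusted over the list alone. The list shifted with camera's preset correlation (adjusted p = 4.16e-26) and with an estimated one (adjusted p = 0.0154), and fry gave an adjusted p of 2.28e-04. The list's mean level was 7.43 ± 0.37 (SD, n = 3) in saline at 1 day, 6.47 ± 0.11 in saline at 6 weeks and 7.82 ± 0.15 in cadmium at 6 weeks, so the saline arrays of 6 weeks lay below those of 1 day.

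Ccl19, a chemokine that draws dendritic cells and T cells, rose by 2.04 (SE 0.28, adjusted p = 0.021) and the class I histocompatibility gene RT1-S3 by 1.70 (SE 0.25, adjusted p = 0.0362). Itgax, an integrin of dendritic cells and macrophages, rose by 1.06 (SE 0.17, adjusted p = 0.0485). Mmp12, the macrophage elastase, was at background in saline and rose by at least 1.31 on the log2 scale (adjusted p = 0.0485). The only fall, of 0.88, was in the unnamed locus LOC102549184. The lower named genes with the smallest p did not pass: Adamts8 at -0.43 with both groups at background (adjusted p = 0.0635), Acsl3 at -0.71 (0.0711), Lrrn1 at -0.82 (0.0711) and Hypk at -0.56 (0.0794). In all, 8 genes rose and 1 fell. Mx1 and Usp18 passed in all 17 alternatives, Irf7 in 12, Ccl19 in 10, and RT1-S3, Mmp12, Itgax and Isg15 in 9, 8, 6 and 9. The count was 500 with array weights, 40 with only the 6 arrays compared and 32 without cadmium replicate 3, and 2 to 4 without any other single array.

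**Figure D1:**
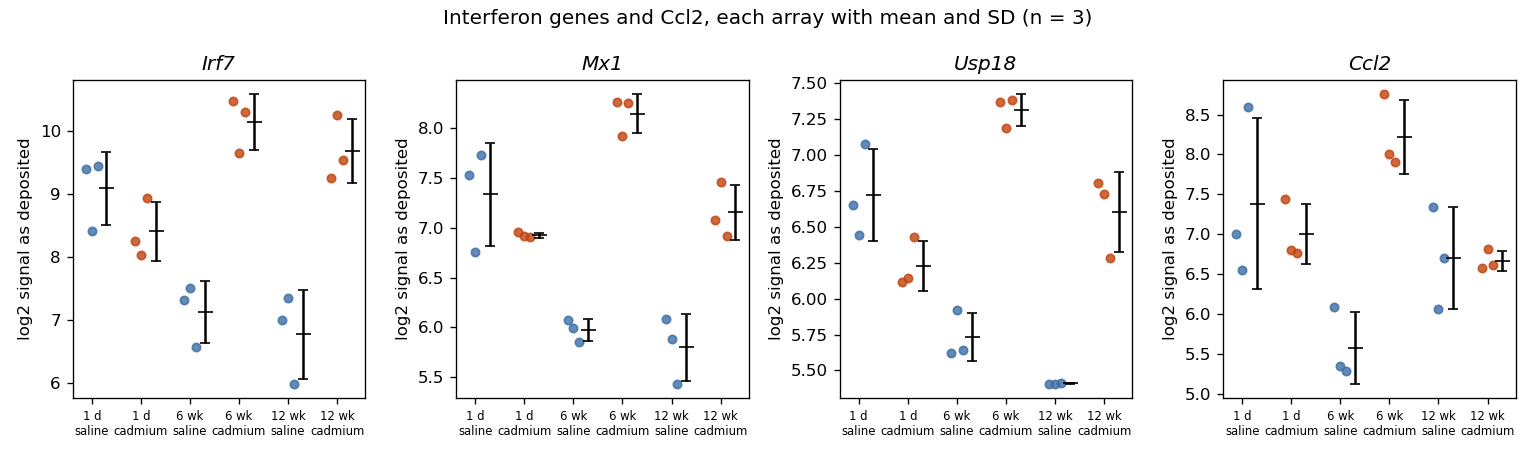
Deposited log2 signal (vertical axis) of Irf7, Mx1, Usp18 and Ccl2 in each of the 18 arrays by time and treatment; points are arrays, and the black mark and bar are the group mean and SD (n = 3). At 6 weeks the 3 cadmium arrays of Irf7 lay above 9.6 and the 3 saline arrays below 7.6, while Ccl2 did not pass the test.

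Inflammatory and macrophage genes were higher at 6 weeks as lists, without a member that passed over all genes. In the inflammatory list 18 of 22 members were on the higher side and 8 passed adjusted over the list alone. Ccl2, which draws monocytes, was 2.64 higher (SE 0.45, adjusted p = 0.0554), and the interferon-induced chemokine Cxcl10 2.54 (SE 0.52, adjusted p = 0.12). The list's camera adjusted p was 1.46e-06, with an estimated correlation the adjusted p was 0.132, and fry gave 0.0142. Macrophage markers had 7 of 13 members higher adjusted over the list alone, among them the signalling adaptors Fcer1g (1.48, SE 0.31) and Tyrobp (1.36, SE 0.30) and the lysosomal marker Cd68 (1.75, SE 0.41). Their camera adjusted p was 6.37e-06, and the adjusted p = 0.467 with an estimated correlation. Lymphocyte genes had a mean of 0.31 (adjusted p = 0.0445, adjusted p = 0.573 with an estimated correlation), with Cd4 at 1.87. Neutrophil genes had a mean of -0.11 with 8 of 10 at background (adjusted p = 0.0483, adjusted p = 0.573 with an estimated correlation).

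Antioxidant and calcium genes of the tubule lay on opposite sides at 6 weeks as lists, without a member that passed over all genes. The antioxidant list, targets of the stress-responsive factor NRF2, had 23 of 24 members on the higher side with a mean of 0.83 and 1 past its threshold adjusted over the list alone, Hmox1 (2.89, SE 0.55, adjusted p = 0.0953 over all genes). Its camera adjusted p was 2.60e-06, and the adjusted p = 0.467 with an estimated correlation. The calcium, phosphate and vitamin D list had 12 of 15 members on the lower side and a mean of -0.79 (adjusted p = 0.0192, adjusted p = 0.254 with an estimated correlation). Cyp24a1, which degrades active vitamin D, was -3.19 apart, the calcium-binding Calb1 -2.51, the sodium-calcium exchanger Slc8a1 -2.13 and the calcium channel Trpv5 -1.90, none of them passing. All 6 podocyte genes were on the lower side with a median of -0.97, Nphs1 (nephrin of the slit diaphragm) at -1.26 (list adjusted p = 9.26e-04, adjusted p = 0.544 with an estimated correlation). Tubular injury markers had a mean of 0.57, cholesterol synthesis 0.34, red blood cells 0.53 and adipose tissue 0.46. For these the camera adjusted p values were 0.013, 9.26e-04, 0.00501 and 0.0171, and with an estimated correlation the adjusted p values were 0.573, 0.544, 0.544 and 0.467. Cell cycle, extracellular matrix and immediate early genes had means of 0.20, 0.40 and 0.36, with adjusted p values of 0.025, 0.0483 and 0.0376, each an adjusted p = 0.874 with an estimated correlation.

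The interferon, antioxidant, inflammatory, macrophage and podocyte lists kept their camera call without each of the 6 arrays of 6 weeks, and none of them moved by 1.5 times. The other calls of that time ended without at least 1 array, extracellular matrix in 5 of 6 cases, immediate early genes and neutrophils in 4, lymphocytes in 3, cell cycle and cholesterol synthesis in 2, and tubular injury, calcium with phosphate and vitamin D, red blood cells and adipose tissue in 1. Immediate early genes ran from 0.24 to 0.59 and cholesterol synthesis from 0.22 to 0.43.

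At 12 weeks Hmox1, Ugt2b7, Abcc2 and Ptgr1 rose steeply with cadmium. Hmox1 stood at 13.89 ± 1.64 (SD, n = 3) with cadmium and 4.85 ± 0.18 with saline, a log2 change of 9.04 (SE 0.55, limma adjusted p = 2.28e-06). Ugt2b7, which couples glucuronic acid to drugs and steroids, stood at 12.66 ± 1.98 against 5.34 ± 0.23, a change of 7.32 (SE 0.65, adjusted p = 1.07e-04). Abcc2, the apical pump for such conjugates, rose by 5.41 (SE 0.61, adjusted p = 0.00106), and Ptgr1, which reduces reactive alkenals, by 4.50 (SE 0.39, adjusted p = 1.07e-04). The aldo-keto reductase Akr1b8 rose by 6.35 (SE 1.23, adjusted p = 0.0434), Ephx1, an epoxide hydrolase, by 3.15 (SE 0.54), napor by 3.57 (SE 0.63) and Irf7 by 2.91 (SE 0.41). Each SE pools the spread of all 6 groups. For Hmox1 and Ugt2b7 the SD was largest in cadmium at 12 weeks, so their SE and adjusted p make too little of the spread there.

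Fewer genes fell at 12 weeks, and by less. Mgll, the monoacylglycerol lipase, fell by 1.31 on the log2 scale (SE 0.25, adjusted p = 0.0432), and Pdzk1ip1, a membrane protein of the proximal tubule, fell by 1.04 (SE 0.19, adjusted p = 0.0283). The others were Ankrd40-ps2 (-0.99), Ccnq (-0.91), the actin-binding Twf1 (-0.85), the transcription repressor Zbtb18 (-0.62), the chromatin organizer Satb1 (-0.61) and Ppp1r2l1 (-0.55). In all, 64 genes rose and 8 fell in limma. With only the 6 arrays of this comparison in the fit, 0 genes passed in limma and 1864 had an unadjusted p under 0.05. The count was 127 with array weights, 43 with median centring and 24 with the replicate numbers as a block, and it ran from 33 without saline replicate 3 to 108 without cadmium replicate 3. Hmox1, Ugt2b7, Abcc2, Ptgr1 and Irf7 each lost their call only with those 6 arrays alone, Akr1b8 kept its call in 5 of 17 alternatives, Ephx1 and napor in 9, Mgll, Pdzk1ip1 and Twf1 in 7, Ccnq in 8, Zbtb18 in 10, Satb1 in 12, Ankrd40-ps2 in 15, and Ppp1r2l1 in 4.

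**Figure D2:**
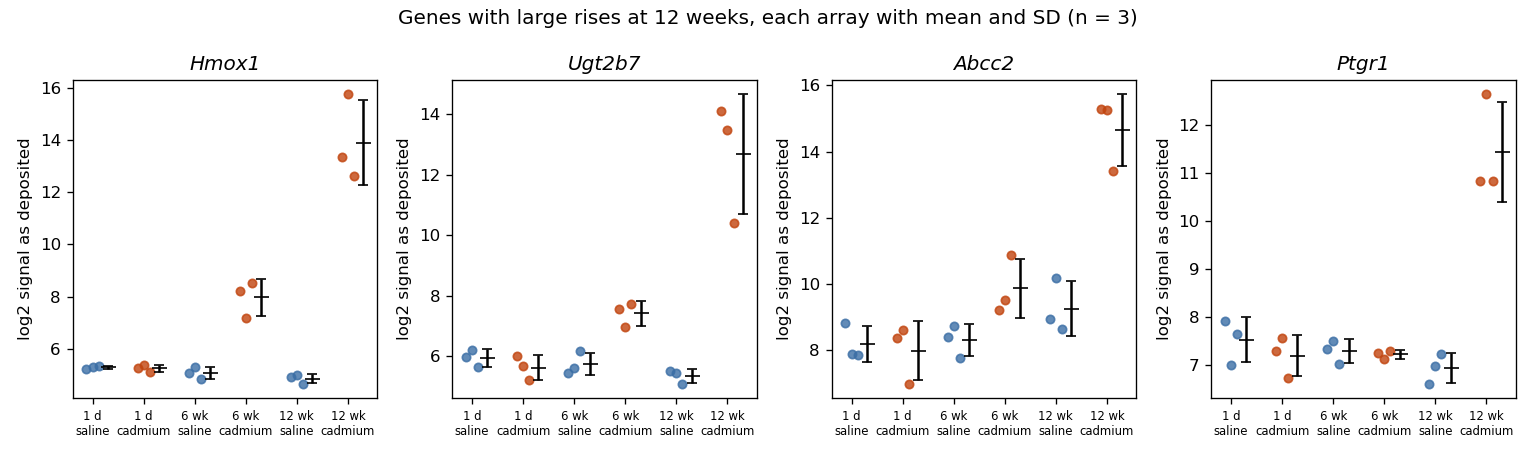
Deposited log2 signal (vertical axis) of Hmox1, Ugt2b7, Abcc2 and Ptgr1 in each of the 18 arrays by time and treatment; points are arrays, and the black mark and bar are the group mean and SD (n = 3). The 3 cadmium arrays of 12 weeks lay above the saline arrays in every panel, with Hmox1 between 12.60 and 15.74.

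As a list the antioxidant genes were higher at 12 weeks, 20 of 24 on that side with a mean of 1.56. Of these, 7 rose past the threshold over all genes and 12 adjusted over the list alone. Besides Hmox1, Akr1b8 and Ephx1 they were Txnrd1 (thioredoxin reductase, 1.53, SE 0.21), the glutathione transferase Gsta3 (1.71, SE 0.25), the export pump Abcc3 (1.44, SE 0.25) and the cystine carrier Slc7a11, at background in saline and at least 1.35 higher. The camera adjusted p was 1.04e-16, the adjusted p = 0.132 with an estimated correlation, and fry gave 0.0074. The interferon list had 18 of 19 members higher with a mean of 0.87. In it 5 rose, Irf7, Usp18 (1.20), Mx1 (1.36), Isg15 (0.71) and Oasl (1.07), and 10 passed adjusted over the list alone (camera adjusted p = 8.03e-15, adjusted p = 0.0808 with an estimated correlation, fry 0.00567). Among p53 targets the kinase Plk2 rose by 2.32 (SE 0.37) and the cell death gene Bax by 0.43 (SE 0.08), with Mdm2 at 0.52 (adjusted p = 0.0844) past the threshold only adjusted over the list alone. Of 17 alternatives Bax kept its call in 5, Isg15 in 9, Mx1 in 12, Plk2 in 14, Txnrd1 and Gsta3 in 15 and Usp18 in 16, and Slc7a11 in 12 of 16. The p53 list had a camera adjusted p of 2.86e-04, and adjusted p = 0.459 with an estimated correlation.

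Tubular metabolism and transport lay on the lower side at 12 weeks without members that passed over all genes. In proximal tubule transport 24 of 25 members were lower, with a mean of -0.83 (camera adjusted p = 2.91e-04, adjusted p = 0.544 with an estimated correlation). The list's mean level was 12.87 ± 0.78 (SD, n = 3) with cadmium and 13.71 ± 0.71 with saline, and the glucose carrier Slc5a2 lay at 7.56 in cadmium replicate 3 and at 9.88 in saline replicate 1, below its level in all other arrays. Fatty acid oxidation had a mean of -0.74 and 5 members lower adjusted over the list alone, with Cyp4a1, a fatty acid hydroxylase, at -3.74 (SE 1.25) and the peroxisomal Ehhadh at -2.26 (SE 0.69; list adjusted p = 1.15e-07, adjusted p = 0.544 with an estimated correlation). The respiratory chain had a mean of -0.16 (adjusted p = 0.0288, adjusted p = 0.889 with an estimated correlation) and the distal nephron and collecting duct 0.43 (adjusted p = 0.0361, adjusted p = 0.874 with an estimated correlation). Without cadmium replicate 1 the distal list turned (-0.02, adjusted p = 0.597), and with the proximal tubule level of each array as a covariate, an alternative chosen after the data were seen, the respiratory chain turned (adjusted p = 0.390).

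Other lists at 12 weeks moved in both directions. Cell cycle genes had 22 of 25 members on the higher side, 3 of them past the threshold adjusted over the list alone, with a mean of 0.33 (camera adjusted p = 7.22e-06, adjusted p = 0.544 with an estimated correlation). Tubular injury had a mean of 0.37 and 3 members higher adjusted over the list alone, Lgals3 (galectin-3) at 0.97 (adjusted p = 0.0612), Fgb at 0.77 and Gpnmb at 1.95 (list adjusted p = 0.00988, adjusted p = 0.573 with an estimated correlation). Extracellular matrix had a mean of -0.39 (adjusted p = 0.00882, adjusted p = 0.856 with an estimated correlation) and endothelium -0.40 (adjusted p = 0.00723, adjusted p = 0.573 with an estimated correlation), with Eng at -1.32 passing adjusted over its list alone. Single members of uncalled lists rose: Slc20a1, a phosphate carrier, by 0.78 (SE 0.14, adjusted p = 0.0252) and the growth regulator Myc by 1.35 (SE 0.23, adjusted p = 0.0199), with calls kept in 8 and 11 of 17 alternatives. Their lists, calcium with phosphate and vitamin D and immediate early genes, had camera adjusted p values of 0.293 and 0.372. In iron handling Tfrc, the transferrin receptor, was 1.61 higher (SE 0.33, adjusted p = 0.0549) and passed adjusted over the list alone (list adjusted p = 0.374).

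Single arrays moved several of the 12-week lists by over 1.5 times. Endothelium stood at -0.11 without cadmium replicate 3 and at -0.61 without cadmium replicate 1, and its call ended in 2 of 6 cases. Tubular injury ran from 0.13 without saline replicate 3 to 0.72 without saline replicate 1 (call ended in 3) and cell cycle from 0.19 to 0.57 without the same arrays, with its call kept. Proximal tubule transport ran from -1.27 to -0.52 with its call kept, the respiratory chain from -0.33 to -0.07 (call ended in 4), extracellular matrix from -0.50 to -0.25 (2) and the distal nephron from -0.02 to 0.66 (2, besides the turn). The antioxidant, interferon, p53 and fatty acid oxidation lists kept their calls without each array and moved by less.

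Metal handling genes did not pass over all genes at any time. Metallothioneins are small proteins that bind cadmium and zinc. Mt1m and Mt2A had group means of 19.87 or more, close to the ceiling of 19.93, in saline as in cadmium, so a rise could not be seen. Mt1 had room only in some groups: its means were 19.11 ± 1.15 (SD, n = 3) with cadmium and 19.16 ± 0.22 with saline at 1 day, 19.93 ± 0.00 and 19.85 ± 0.07 at 6 weeks, and 19.92 ± 0.01 and 19.47 ± 0.43 at 12 weeks. The cadmium arrays of 6 and 12 weeks lay at the ceiling or within 0.02 of it, so the differences of Mt1 there are truncated and no test of them is given. Mt4 lay at background and Mt3 between 4.37 and 4.61. The zinc exporter Slc30a1 was -0.13, 1.15 and 1.23 apart at the 3 times (SE 0.44 each, adjusted p = 0.429 at 6 weeks and 0.397 at 12 weeks). At 12 weeks the zinc importer Slc39a10 was -0.57 apart (SE 0.15, adjusted p = 0.168) and Slc39a4, at background in saline, at least 0.54 higher (adjusted p = 0.216). Both passed adjusted over the list alone. The 12-week changes of the others were -0.95 for Slc39a8, 0.71 for Slc30a2, -0.42 for Slc30a4, 0.19 for Slc39a14, -0.17 for Mtf1, 0.15 for Slc39a1 and 0.01 for Slc11a2, with Slc30a10 at background. The list's camera adjusted p values were 0.843, 0.374 and 0.823, and at 12 weeks its median was -5.04e-04 and its mean 0.09.

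Several lists were called at none of the 3 times. At 12 weeks their mean changes were 0.02 for autophagy and lysosome (median -0.05), 0.02 for glucocorticoid response, 0.03 for adrenal cortex, whose 6 measured genes lay at background, and 0.06 for urothelium. Their camera adjusted p values were 0.998, 0.497, 0.686 and 0.475. The circadian clock list, transcription factors of the daily rhythm, had means of -0.29, -0.10 and 0.16 at the 3 times with camera adjusted p values of 0.277, 0.546 and 0.879. Its levels set arrays of 1 group apart: Bmal1, which peaks opposite to Dbp, was 9.16 in cadmium replicate 3 at 6 weeks against 5.82 and 5.62 in the other cadmium arrays of that time. At 12 weeks it was 8.59 to 9.77 in saline, and 8.70, 6.22 and 8.79 in cadmium. With Bmal1 minus Dbp of each array as a covariate, an alternative chosen after the data were seen, 67 genes passed at 6 weeks and 47 at 12 weeks, 9 and 43 of them among the genes called without it.

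**Figure D3:**
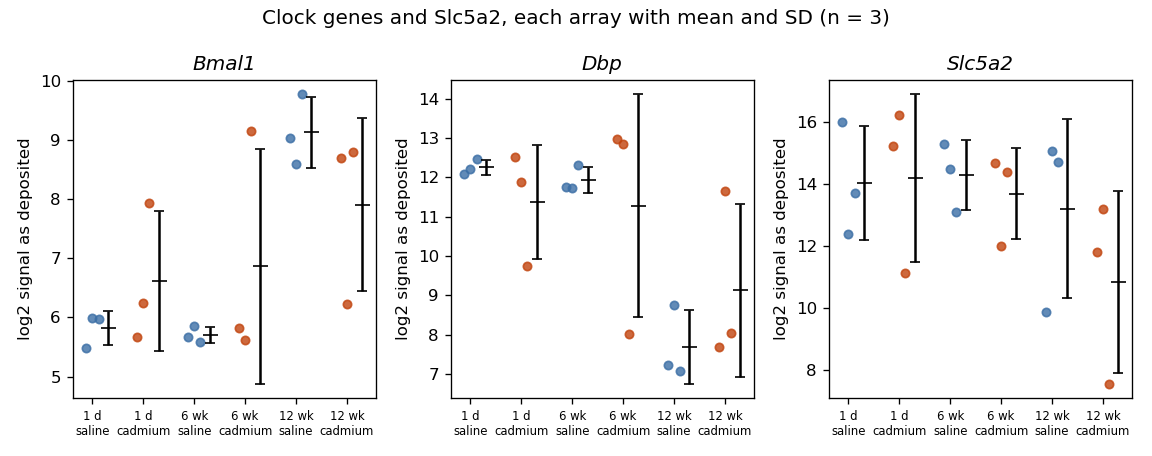
Deposited log2 signal (vertical axis) of Bmal1, Dbp and Slc5a2 in each of the 18 arrays by time and treatment; points are arrays, and the black mark and bar are the group mean and SD (n = 3). Bmal1 stood at 9.13 ± 0.60 in saline at 12 weeks and 5.71 ± 0.14 in saline at 6 weeks, and Slc5a2 ranged from 7.56 to 16.24.

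Averaged over the 3 times, genes that rose at 12 weeks led. Hmox1 rose by 3.96 (SE 0.32, adjusted p = 9.42e-05), Ugt2b7 by 2.90 (SE 0.37, adjusted p = 0.00905), Abcc2 by 2.25, Irf7 by 1.75 and Ptgr1 by 1.36. Ptgr1 lost its call in 17 of 28 alternatives and Abcc2 in 12, and the other 3 kept it in all. In limma 18 genes rose and none fell, and 1390 had an unadjusted p under 0.05. The lower genes with the smallest p did not pass: Satb1 (-0.31, adjusted p = 0.0657), Acsl3 (-0.40) and Camk2n1 (-0.62). With an estimated correlation 4 lists shifted, interferon response (mean 0.67, adjusted p = 0.00348), antioxidant (0.74, 0.0347) and inflammatory signalling (0.21, 0.0347) upward, and calcium, phosphate and vitamin D (-0.36, 0.0347) downward. The count of genes ran from 6 without saline replicate 3 of 6 weeks to 30 without cadmium replicate 3 of 12 weeks.

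The cadmium change differed between times for a few genes. Mx1 and Usp18 changed more at 6 weeks than at 1 day, by 2.59 (SE 0.31, adjusted p = 0.00869) and 2.08 (SE 0.23, adjusted p = 0.00475). From 1 day to 12 weeks the change grew by 9.08 for Hmox1 (SE 0.78, adjusted p = 2.29e-04), 7.63 for Ugt2b7 (SE 0.92), 5.61 for Abcc2 (SE 0.86), 4.85 for Ptgr1 (SE 0.56) and 3.59 for Irf7 (SE 0.58). Of these, Abcc2 lost its call in 12 of 21 alternatives and Irf7 in 11, and the others kept it in all. Between 6 and 12 weeks it grew by 6.15 for Hmox1 (SE 0.78, adjusted p = 0.0102) and 4.57 for Ptgr1 (SE 0.56, adjusted p = 0.0102), calls lost in 2 and 1 of 21 alternatives. In limma 2, 9 and 3 genes passed in the 3 differences, all of them higher at the later time, and 1472, 1046 and 2214 had an unadjusted p under 0.05. The lower ones with the smallest p did not pass: Pbk-ps1 (-0.85), Rag2 (-0.84) and Mir191 (-0.57) for 6 weeks against 1 day, Ankrd40-ps2 (-1.05), Zbtb18 (-0.76) and Kncn (-1.11) for 12 weeks against 1 day, and C3ar1 (-2.22), Trpc6 (-1.09) and Slc15a3 (-1.12) for 12 weeks against 6 weeks. The interferon list differed between 6 weeks and 1 day by a mean of 1.55 (adjusted p = 0.0245 with an estimated correlation). Without saline replicate 2 of 6 weeks, 0 genes passed in limma between 6 and 12 weeks and 3075 had an unadjusted p under 0.05.

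Saline kidneys changed with time as well. Collagen and proliferation genes fell from 1 day to 6 weeks: Col1a1, a chain of type I collagen, fell by 3.14 on the log2 scale (SE 0.49, adjusted p = 0.0139), the proliferation marker Mki67 fell by 2.92 (SE 0.54, adjusted p = 0.0269), and Col1a2, Col3a1 and Smoc2 changed by -2.56, -2.53 and -2.27. Rises were smaller: Adcy1, an adenylate cyclase, 1.64, Cnnm1 1.12, Lrrn1 0.79, Sptan1 0.54, and Trpc5 from background by at least 0.71. In all 9 genes rose and 102 fell. By 12 weeks 7 had risen and 57 fallen against 1 day, with the ubiquitin ligase Rnf125 (3.02), the immunoglobulin receptor Pigr (2.31), Cnnm1 (1.57), the cholesterol exporter Abca1 (1.05) and Cemip (1.01) higher, and Col1a1 (-3.17), Col3a1 (-2.72), Ptgs2 (-2.70), Col1a2 (-2.59) and Irf7 (-2.31) lower. Of 25 cell cycle genes 15 fell by 6 weeks and 6 by 12 weeks (adjusted p = 0.0423 with an estimated correlation at both). Interferon genes fell in 3 and 4 members (adjusted p = 0.0521 and 0.0423 with an estimated correlation), and extracellular matrix in 5 and 4 (adjusted p = 0.158 and 0.231 with an estimated correlation).

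Between 6 and 12 weeks 0 genes passed in saline in limma, and 1854 had an unadjusted p under 0.05. The smallest p values belonged to Rplp1l3 (0.44, both groups at background), Rnf125 (3.24) and Rars1 (1.03) on the higher side and Zfp597 (-0.46), Rngtt-ps1 (-0.74) and Lrrn1 (-0.81) on the lower side, each with an adjusted p of 0.224. Age and harvest day could not be separated in these groups. Of 16 alternatives the calls at 6 weeks against 1 day were kept in 13 for Col1a1, 12 for Col1a2 and Col3a1, 11 for Adcy1, 10 for Smoc2, 9 for Mki67 and Cnnm1, 8 for Trpc5, 7 for Lrrn1 and 6 for Sptan1. At 12 weeks against 1 day they were kept in 14 for Cnnm1, 12 for Col1a1 and Col3a1, 11 for Abca1 and Col1a2, 10 for Cemip, 9 for Irf7, 7 for Pigr and Ptgs2 and 6 for Rnf125. The saline arrays are shared by these comparisons and those with cadmium. With only the 6 arrays compared, 8 genes passed at 6 weeks and 2 at 12 weeks against 1 day, none of them a named collagen gene. Without single arrays the count at 6 weeks against 1 day ran from 19 to 118, and that at 12 weeks from 8 to 127. With the clock covariate 0 genes passed in limma at 12 weeks against 1 day and 1167 had an unadjusted p under 0.05. There Col1a1 stood at -3.17 (SE 0.72, before 0.49) and Cnnm1 at 1.73 (SE 0.29, before 0.20), while Rnf125 went from 3.02 to 1.54 (SE 0.64, before 0.58). All 3 saline arrays of 12 weeks had a shifted clock, so this covariate nearly coincides with the group.

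Across genes the cadmium changes of different times were barely related. Pearson's r was -0.211 between 1 day and 6 weeks, 0.0345 between 1 day and 12 weeks and 0.0683 between 6 and 12 weeks, and Spearman's rho was -0.173, 0.0903 and -0.0817, so r and rho differed in sign for the last pair. These are correlations across 22084 genes, which are not independent replicates. Of the genes called at 6 and 12 weeks 5 were shared, Irf7, Isg15, Mmp12, Mx1 and Usp18, all higher at both times. Independent genes would share 0.0232 by chance. Irf7, Isg15, Mx1 and Usp18 belong to the interferon list, whose genes moved together, so they are not independent.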

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

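The splits for the agreement between times, both clock covariate tests and the proximal tubule covariate test were chosen only after the result was seen. So were the comparisons of 6-week cadmium with saline of other times, the array levels set beside the clock and the use of the alternatives for the first pattern.

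The cadmium change differed between times by a test of the difference itself for the following genes, which is what flagged them. Between 6 weeks and 1 day these were Mx1 (2.59, SE 0.31, adjusted p = 0.00869) and Usp18 (2.08, SE 0.23, adjusted p = 0.00475). Between 12 weeks and 1 day they were Hmox1 (9.08), Ugt2b7 (7.63), Abcc2 (5.61), Ptgr1 (4.85), Irf7 (3.59), Usp18 (1.69), Bach1 (1.31), Mypn (1.16) and LOC102552091 (1.04). Between 12 and 6 weeks they were Hmox1 (6.15), Ptgr1 (4.57) and LOC102552091 (1.11). Bach1, Mypn and LOC102552091 are named because they were flagged, after their values were seen. The interferon list differed between 6 weeks and 1 day by a mean of 1.55 (adjusted p = 0.0245 with an estimated correlation).

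Other splits of the arrays show how far chance can be excluded. For the 3 comparisons of cadmium with saline and the 3 of saline between times the 6 arrays make 10 splits, too few for a share under 0.05. At 6 weeks 1 split, the real one, gave 9 genes and the highest other gave 0, and at 12 weeks 1 split gave 72 and the highest other 46. At 1 day all 10 splits gave 0. In saline 1 split gave 111 genes at 6 weeks against 1 day and 1 gave 64 at 12 weeks against 1 day, with 0 as the highest other in both, and all 10 splits gave 0 between 6 and 12 weeks. Of 100 splits drawn within times, the real one included, 2 gave at least the 18 genes of the average (highest other 28). For the 2 genes of 6 weeks against 1 day 2 splits gave at least as many (highest other 14). Both shares lie under 0.05, so chance seldom gives such counts, but it can. The shares were not adjusted for the number of split tests. For the 9 genes of 12 weeks against 1 day 11 splits gave as many. Some draws keep the real 12-week groups, 1 of their 10 splits, and with them any change of that time alone. A share under 0.05 was thus harder to reach, though the difference between 6 weeks and 1 day, drawn in the same way, reached it. The rule set beforehand took a share of 0.05 or more as a sign of chance. Chance is therefore not excluded for these 9 genes. The highest other gave 880, which points to a structure of the samples, and what that split follows was not tested. For the 3 genes of 12 against 6 weeks 8 splits gave as many (highest other 10). The same limit and the same rule hold there, so chance is not excluded for these 3 genes either. Of 100 splits, the real one included, 3 gave at least the 35 list calls over the 3 times (highest other 40). Chance thus seldom gives so many list calls, but it can. Correlations between times as large as those seen arose in 40, 96 and 76 of 100 splits (1 day with 6 weeks, 1 day with 12 weeks, 6 with 12 weeks), with 0.482, 0.514 and 0.470 as the largest others, so chance cannot be excluded for any of the 3.

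The first pattern weighed is the 64 genes that rose with cadmium at 12 weeks. With the proximal tubule level of each array as a covariate a median of 101.6% of the log2 change was left (quartiles 95.5% and 107.2%). The mean change was 1.72 before and 1.77 after. With Bmal1 minus Dbp as a covariate a median of 98.2% was left (quartiles 96.4% and 102.6%), with a mean of 1.72 before and 1.69 after. These genes were chosen for changes large beside the spread within groups, which sets the slope of a covariate. A large loss was thus hardly within reach, so neither covariate decides on fewer proximal tubule transcripts or another phase of the clock. In Bmal1 minus Dbp cadmium replicates 1 and 3 of 12 weeks stood at 1.02 and 0.73, and saline between -0.17 and 2.70. All 72 called genes had separate groups. They were chosen for a difference between these groups, which favours separate groups, so this does not decide on the clock. Hmox1 stood at 13.35 and 12.60 in cadmium replicates 1 and 3 of 12 weeks, against a saline mean of 4.85 (SD 0.18). For Hmox1 these levels argue against the clock as the whole cause. For the other called genes the clock is left open. Of the 64 calls 48 remained with the first covariate and 39 with the second. The others ended as the median SE grew from 0.192 to 0.211 and 0.203 while the changes stayed. A difference in scale between arrays is argued against as the whole cause, since 61 of the 72 calls of this comparison, higher and lower, remained with quantile normalization and 42 with median centring, and the change of Hmox1 lay between 8.12 and 9.69 in all 17 alternatives. Without each single array of the 6 between 29 and 59 of the 72 calls remained, and the count ran from 33 to 108. This argues against a single mislabelled array as the whole cause. Ended calls are not in themselves a sign of such an array, since the changes of named genes among them stayed. Over all 17 alternatives Akr1b8 lay between 5.63 and 7.67, napor between 3.08 and 4.29 and Bax between 0.37 and 0.48. For unnamed genes whose calls ended it is left open. The authors' summarization is not stated and leaves the size of the changes on this scale open. An effect of cadmium stays open as a hypothesis.

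The second pattern is the 17 interferon genes higher with cadmium at 6 weeks adjusted over the list alone. With the clock covariate a median of 100.7% of the change was left (quartiles 98.97% and 103.3%, mean 1.39 before and 1.42 after). There 4 calls over all genes became 6. The genes were chosen for their change in these arrays, so a large loss was hardly within reach. Another phase of the clock is argued against by the array levels. At 6 weeks Bmal1 minus Dbp was shifted only in cadmium replicate 3 (1.15). The list's mean was 7.98 and 7.82 in cadmium replicates 1 and 2, and at most 6.59 in saline of 6 weeks. With the mean of macrophage markers as a covariate a median of 83.5% was left (quartiles 66.3% and 92.6%), with a mean change of 1.39 before and 1.09 after. The 4 calls became 0 there, since the changes shrank and the median SE grew from 0.258 to 0.322, so the calls did not hold. The macrophage mean at 6 weeks was 7.72 ± 0.39 (SD, n = 3) with cadmium and 6.88 ± 0.20 with saline. The same choice of genes limits this covariate, so it does not decide on more macrophage transcripts in the cadmium arrays. A low level in the 6-week saline arrays alone is argued against: set against saline at 12 weeks, a median of 107.3% of the change was left (quartiles 93.1% and 120.1%; mean 1.39 before and 1.46 after, median SE 0.258), and 4 genes passed over all genes. The interferon list stood at 6.46 ± 0.13 (SD, n = 3) in saline at 12 weeks and 6.47 ± 0.11 at 6 weeks. Against saline at 1 day a median of 34.9% of the change was left (quartiles 12.9% and 40.5%, mean 0.42, median SE 0.258). In that comparison 0 of the 17 genes passed over all genes in limma. This restates the higher level of saline at that time. Both comparisons cross ages. A fall with age in saline that cadmium animals did not share and a rise with cadmium were not told apart, nor was harvest day.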

How the results depend on the processing

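The clock and proximal tubule covariates were chosen only after the result was seen; the other alternatives were planned.

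Counts that left a range of 1.5 times the reported one are given by setting. Quantile normalization gave 14 genes for 12 weeks against 1 day in the cadmium change and 1 for saline at 12 against 6 weeks, and at 12 weeks 54 higher and 14 lower genes in place of 64 and 8. Median centring gave 43 at 12 weeks, 11 for the average and 30 for saline at 12 weeks against 1 day. Every probe set gave 3 at 6 weeks, 132 at 12 weeks, 7 for the average, and 53 and 24 for saline at 6 and 12 weeks against 1 day. Trend and robust fitting gave 14 at 6 weeks and 16 for 12 weeks against 1 day in the cadmium change. Array weights, which ran from 0.416 to 3.59, gave 500 at 6 weeks, 127 at 12 weeks and 59 for the average, 7, 26 and 14 for the differences (6 weeks against 1 day, 12 weeks against 1 day, 12 against 6 weeks), and 341, 131 and 19 for saline in the same order. The replicate numbers as a block gave 3 at 6 weeks, 24 at 12 weeks and 7 for the average. Only the arrays compared gave 40 at 6 weeks, 6 of the 9 among them, 0 at 12 weeks in limma (1864 with an unadjusted p under 0.05, 4 residual degrees of freedom), and 8 and 2 for saline at 6 and 12 weeks against 1 day.

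The clock covariate gave 67 at 6 weeks, 47 at 12 weeks and 0 for saline at 12 weeks against 1 day in limma (1167 with an unadjusted p under 0.05). The proximal tubule covariate gave 18 for 12 weeks against 1 day and 5 for 12 against 6 weeks in the cadmium change, and 91 at 12 weeks, 53 of the 72 among them. With an estimated correlation 1 list call remained of 35. The proximal tubule covariate turned proximal tubule transport at 12 weeks (adjusted p = 0.971), as its construction requires, and the respiratory chain (adjusted p = 0.390).

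Leaving out single arrays moved the counts from 2 (without saline replicate 2) to 32 (without cadmium replicate 3) at 6 weeks, 33 (saline replicate 3) to 108 (cadmium replicate 3) at 12 weeks, and 6 (6-week saline replicate 3) to 30 (12-week cadmium replicate 3) for the average. The differences moved from 2 to 5 for 6 weeks against 1 day, 6 to 20 for 12 weeks against 1 day, and 0 (limma, 3075 with an unadjusted p under 0.05) to 17 for 12 against 6 weeks. Saline moved from 19 to 118 at 6 weeks against 1 day, 8 to 127 at 12 weeks against 1 day, and 0 (limma, 1346 with an unadjusted p under 0.05 without 6-week saline replicate 1) to 10 for 12 against 6 weeks. Adjusted p values of lists ranged from 0.0148 to 0.869 for proximal tubule transport, 1.62e-06 to 0.468 for extracellular matrix (called in the other direction without saline replicate 3) and 7.09e-04 to 0.559 for sex-linked genes at 1 day, and 0.00103 to 0.597 for the distal nephron at 12 weeks, each turned without 1 array. The correlation across genes ranged from -0.320 to 0.115 between 1 day and 6 weeks and from -0.224 to 0.222 between 1 day and 12 weeks.

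Of the values of called named genes 545 of 704 kept their call under other settings and 159 lost it, and without single arrays 303 of 522 kept it and 219 lost it, with 0 turned. Of those not called, 71 of 4523 gained a call under other settings and 16 of 2604 without single arrays. Of the values of the called lists 147 of 210 kept their call, 61 lost it and 2 turned under other settings, and without single arrays 544 of 630 kept it, 83 lost it and 3 turned. Of those not called, 11 of 348 gained a call, and without single arrays 30 of 1044 did and 1 was called in the other direction. Values passing in neither fit changed sign in 44 and 94 cases for genes and 24 and 76 for lists. An offset of 16 was not run, since the values are log2.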

Other observations

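These are values outside the tests above, looked at after the data were seen, and no explanation was tested for them.

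The arrays split on a daily clock gene pair across groups. Bmal1 minus Dbp lay between -1.81 and 2.70 in 7 arrays, the 3 saline and 2 of the cadmium arrays of 12 weeks, 1 cadmium array of 6 weeks and 1 of 1 day, and at -5.43 or below in the other 11. The first principal component of the 18 arrays held 24.3% of the variance and the second 18.1%. Between 0 and 174 probe sets per array lay at the ceiling of the scale, 174 in cadmium replicate 1 of 12 weeks.

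The metallothioneins Mt1m and Mt2A lay near that ceiling in saline as in cadmium, so these arrays cannot show whether they rose. Mt1 reached the ceiling in the cadmium arrays of 6 and 12 weeks, so the size of any rise cannot be read there.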
